A study of Mus musculus with 16 samples.

How the data were processed

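RNA was sequenced from projection neurons of the mouse cerebral cortex. The labels describe transgenic mice that carry human SOD1, either with the ALS-linked G93A change (strain B6SJL-Tg(hSOD1*G93A)1Gur/J) or as the wild-type gene (strain B6SJL-Tg(hSOD1*WT)2Gur/J), at postnatal days 5 and 7. Dissociated cortex was fixed, stained with antibodies to the nuclear proteins CTIP2 (encoded by Bcl11b) and SATB2, and sorted by flow cytometry, per the labels. Full-length cDNA was amplified from the sorted cells' RNA and sequenced as paired ends. The 16 libraries form 4 groups of 4, namely Ctip2+ and Satb2+ neurons of each genotype, and each group holds 2 libraries of each age.

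The only processed file at hand is a table of 32310 entries with 1 FPKM value per gene and group (fragments per kilobase of transcript, scaled by the number of mapped fragments), made by the authors. Reads were aligned to the mouse genome build mm9 with TopHat2, and quantified and tested with Cuffdiff 2.2.1, according to the authors' processing notes. The annotation, the filters and the scaling between libraries are not stated. Cuffdiff's test statistic, a signed score, was deposited by the authors beside each log2 fold change. The p-value and q-value of each gene are those of the authors' Cuffdiff test, as deposited, for G93A against hSOD1WT within each sorted population. The smallest p in the authors' deposited table is 5e-05, shared by 166 tested genes in Ctip2+ and 117 in Satb2+ neurons.

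The table holds no value for a single library. No spread between replicates, no test of replicates, no comparison of the ages and no left-out library could be computed, and the read depth per library is unknown. The difference between the populations was not tested. An error per gene can be had from the fold change and Cuffdiff's statistic, but its scale is open: at a deposited p near 0.05 the median statistic was 0.977 in Ctip2+ and 0.976 in Satb2+ neurons, where a normal score would be 1.96. The authors' q below 0.05 was therefore taken as the threshold, which was the rule set for this kind of file. Called genes are those past it, and only genes that Cuffdiff tested were counted. The deposited q values did not equal a Benjamini-Hochberg adjustment over either comparison alone or over both together. An adjustment within each comparison gave exactly the authors' own population flags in all 32310 entries, and its counts are given beside those by q. The largest deposited q among genes called by that stricter adjustment was 0.0142 in Ctip2+ and 0.0107 in Satb2+ neurons, so any gene reported here with a larger q is not called by it.

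Start positions were raised by 1, because table spans equalled reference gene spans in 5099 of 13473 genes when the start was counted from 0 and in 337 when it was counted from 1. An entry can share its locus with others, which was the case for 11524 entries. The deposited fold change differed by over 0.001 from the ratio of the deposited values in 12 entries for Ctip2+ and 27 for Satb2+ neurons, and folds given here are ratios of the values, while log2 fold changes are as deposited. A fold against a group listed at 0 is not given.

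The following choices were made before the data were examined: the comparisons, the threshold, the 31 gene lists and the rule for naming genes. Named genes are Sod1, Bcl11b, Satb2 and Fezf2. To these the rule adds, per comparison, the 12 called genes with the largest log2 fold change in each direction and at least 1 FPKM in the higher group, leaving out symbols of the kinds Gm, Rik, Mir and Snor. It also adds up to 4 members of each list, called members first. Genes named for being called in both populations, list members beyond those 4, and genes of the comparison between sorts were chosen after their values were seen.

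The lists cover cell types (subcerebral, corticothalamic and callosal projection neurons, interneurons, striatal neurons, astrocytes, oligodendrocyte lineage, microglia, vascular cells, blood, cycling progenitors), neuronal function (immediate early genes, sodium, potassium and calcium channels, glutamate receptors, GABA and glycine receptors, presynaptic and postsynaptic density genes) and cell state (unfolded protein response, heat shock, antioxidant, proteasome, autophagy and lysosome, respiratory chain, sterol synthesis, interferon response, ALS genes, axon cytoskeleton and transport, p53 and apoptosis). The last list holds Y-linked genes and Xist. Dctn1, Kif5a, Nefh, Optn, Sqstm1, Stmn2 and Unc13a each stand in the ALS list and in another one. The 4 lists of the authors (sodium channels, potassium channels, glutamatergic synapse, synaptic transmission) come from the deposited table, and how they were chosen is not stated.

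For each list, called members were counted in each direction, and the count adjusted over the list alone was taken beside it. A one-sided Fisher's exact test set the called members against all other tested genes, with Benjamini-Hochberg adjustment over the 140 list tests (each list, direction and population). The list's median log2 fold change was placed as a percentile among 10000 random lists of the same size, drawn from 10 strata of expression, as a description. Lists with fewer than 3 tested members have no median. These tests treat genes as independent, which genes of one pathway are not. In a simulation, lists of 20 genes among 13059 had fold changes drawn independently and with the same spread at every expression level. Of unshifted lists, 5% fell outside the 2.5th to 97.5th percentile, and 96% of lists shifted by 0.4 on the log2 scale were found. These shares check the procedure and are not error rates for the real lists.

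The sorts were compared by the log2 ratio of FPKM + 1 between Ctip2+ and Satb2+ neurons of one genotype, over entries with at least 1 FPKM in either. No test exists for this comparison, and a 4-fold ratio, chosen after the file was seen, marks large differences. Transcript GC content and length came from the longest coding transcript of GENCODE M21 (GRCm38), matched by symbol or RefSeq synonym. A value was found for 10907 genes, 89.2% of the 12230 genes tested in both populations with at least 1 FPKM in all groups. Ranks of genes by GC content and length were cut into 10 equal parts.

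Alternatives covered stricter thresholds, low-value filters, pseudocounts, quantile normalization of the group values, the adjustment within each comparison, genes alone at their locus, and random lists matched on GC content. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.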

Results

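Gene expression was measured by RNA sequencing in projection neurons sorted from the cortex of transgenic mice with human SOD1, either mutant (G93A, which causes ALS) or wild-type (hSOD1WT). Ctip2+ neurons, the labels' corticospinal neurons, project below the cortex, and Satb2+ neurons connect cortical areas. The 16 libraries fell into 4 groups of 4, each with 2 libraries from postnatal day 5 and 2 from day 7. The authors' deposited table gives 1 pooled FPKM value per gene and group, so no error between replicates can be given and the ages cannot be compared. Read totals are not in the file. Group sums of FPKM in the authors' deposited table were 543373 and 543222 for Ctip2+ hSOD1WT and G93A neurons, and 486748 and 520114 for Satb2+ hSOD1WT and G93A neurons. Positions are on the mouse build mm9.

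The comparison of the sorts asks whether each population carried its own identity in both genotypes. Of 13 subcerebral genes in hSOD1WT, 9 were at least 2-fold higher in Ctip2+ neurons and 1, Igfbp4, at least 2-fold higher in Satb2+ neurons. Of 20 callosal genes, 15 were at least 2-fold higher in Satb2+ neurons and 2, Cpne4 and Dkk3, at least 2-fold higher in Ctip2+ neurons. Bcl11b, which encodes CTIP2 (chromosome 12, 109148613 to 109241624), stood at 63.9 FPKM in hSOD1WT and 58.5 FPKM in G93A Ctip2+ neurons in the authors' deposited table, against 0.236 and 0.288 FPKM in Satb2+ neurons. Fezf2, a regulator of subcerebral fate (chromosome 14, 13174406 to 13178379), stood at 153 and 197 FPKM against 15.1 and 14.7 FPKM in the authors' deposited table. Crym, a thyroid hormone binding protein, stood at 259 and 275 FPKM against 1.21 and 1.5 FPKM in the authors' deposited table. In the other direction, Cux2 stood at 0.951 and 0.595 FPKM in Ctip2+ against 21.3 and 20.3 FPKM in Satb2+ neurons in the authors' deposited table. Lhx2 stood at 2.14 and 1.01 against 42.7 and 39.9 FPKM, and Lpl, lipoprotein lipase, at 3.99 and 5.32 against 132 and 151 FPKM in the authors' deposited table. Satb2 itself (chromosome 1, 56850825 to 57028178) was not restricted to its sort, with 19.0 and 15.2 FPKM in Ctip2+ against 67.3 and 67.4 FPKM in Satb2+ neurons in the authors' deposited table.

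**Figure D1:**
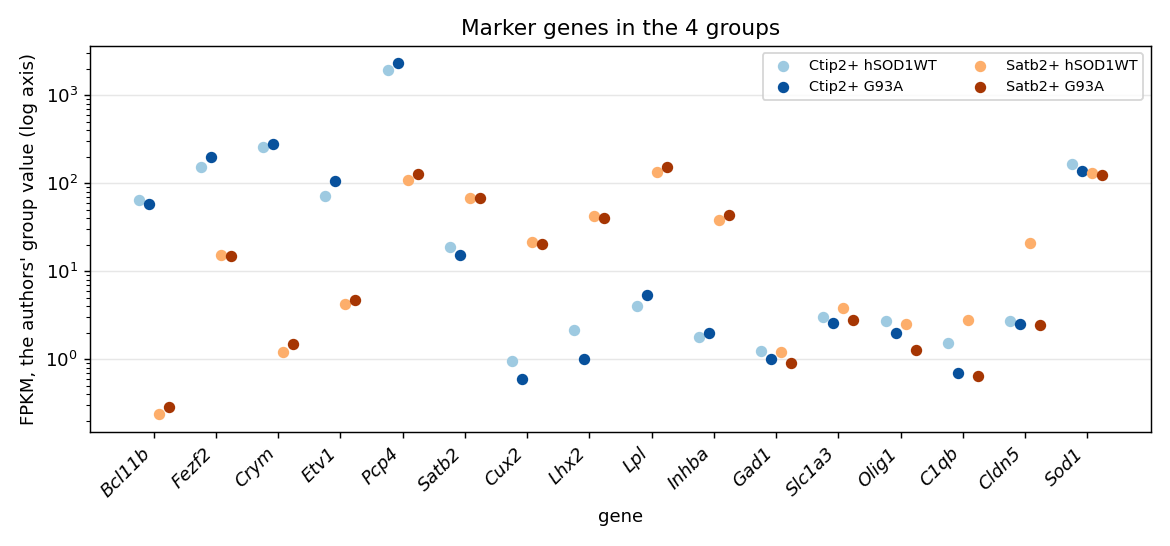
FPKM (log axis) of 16 marker genes in the 4 groups, 1 point per group, from the authors' deposited table, with no error because the table holds pooled values. Bcl11b, Fezf2, Crym, Etv1 and Pcp4 sit higher in Ctip2+ neurons, Satb2, Cux2, Lhx2, Lpl and Inhba sit higher in Satb2+ neurons, and Cldn5 stands at 20.9 FPKM in Satb2+ hSOD1WT neurons against 2.44 FPKM in Satb2+ G93A neurons.

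In hSOD1WT, 128 entries were at least 4-fold higher in Ctip2+ and 97 in Satb2+ neurons, and in G93A the counts were 168 and 145. Of these, 93 were at least 4-fold higher in Ctip2+ neurons in both genotypes, and 74 in Satb2+ neurons. The log2 ratios between the sorts correlated across 14472 entries (Pearson r = 0.767), which are genes and not independent replicates. The median log2 ratio of Ctip2+ over Satb2+ in hSOD1WT was 1.75 for the subcerebral list, above all random lists of like expression, and -2.57 for the callosal list, below all of them. With log2(value + 0.1) the 4-fold counts became 337 and 315 in hSOD1WT and 449 and 356 in G93A.

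G93A against hSOD1WT in Ctip2+ neurons asks what differs between the mutant and the wild-type SOD1 lines in the sort that the labels call corticospinal neurons. Each genotype came from its own transgenic line, so in both populations other differences between the lines cannot be told apart from the G93A change. Of 18 tested genes of the postsynaptic density, 6 fell and 12 did not pass the test. Endoplasmic reticulum chaperone, sterol synthesis and listed callosal genes included members that rose, and subcerebral and corticothalamic genes other than S100a10, Etv1, Tle4 and Ntsr1 did not pass the test. Of 13851 tested genes, 389 were called higher and 539 lower in the authors' deposited table, 928 in all or 6.70%. Adjustment within the comparison left 177 higher and 299 lower. The smallest fold called was 1.40 in the authors' deposited table.

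Of 18 tested postsynaptic density genes, 6 fell, none rose and 12 did not pass the test in the authors' deposited table. The count adjusted over the list alone was 6, and the adjusted p of Fisher's exact test was 0.00147. The fall reached 2.5-fold for Dlgap3 (11.2 to 4.48 FPKM, q = 0.000711) and 2.31-fold for Dlg4, the scaffold PSD-95 (16.5 to 7.13 FPKM, q = 0.000711), in the authors' deposited table. Shank2 (2.16-fold), Nrgn, which binds calmodulin (459 to 253 FPKM, 1.82-fold), Homer1 and Shank1 fell too in the authors' deposited table. The list's median log2 fold change was -0.33, at percentile 0.010 of random lists, with 15 members below 0 and 3 above. GC-rich transcripts moved the same way: among the 10% of genes with the highest GC content, 177 of 1091 (16.2%) were called lower and 12 higher in the authors' deposited table, and the median GC content of the postsynaptic list was 54.1%.

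Among ion channel genes, Scn1b, a sodium channel beta subunit, fell 2.53-fold (52.2 to 20.7 FPKM, q = 0.000711) as the only called member of 9 tested sodium channel genes in the authors' deposited table. Of 57 tested potassium channel genes, 4 rose (Kcnab1, Kcnd2, Kcna4 at q = 0.0151, Kcnip1 at q = 0.0437) and 4 fell (Hcn2, Kcnab2, Kcnn1 at q = 0.0359, Kcnb2 at q = 0.0398) in the authors' deposited table. Hcn2, a pacemaker channel, fell 2.83-fold (14.1 to 4.98 FPKM, q = 0.000711), and Kcnab1 rose 1.72-fold (q = 0.00521) in the authors' deposited table. The calcium channel list also holds genes of calcium pumps, such as Atp2b1. Of its 29 tested genes, Cacnb4 (1.77-fold) and Atp2b1 (q = 0.0230) rose and Cacnb1 (q = 0.0158) and Cacna1h (q = 0.0455) fell in the authors' deposited table. Of 23 glutamate receptor genes, Gria4 rose 1.67-fold and Grin1 fell 1.57-fold in the authors' deposited table. Gabra4 rose 1.68-fold as the only called one of 18 GABA and glycine receptor genes in the authors' deposited table. Of 23 presynaptic genes, the vesicular glutamate transporter Slc17a6 rose 1.67-fold, and Syn1 (q = 0.0408) and Syt4 (q = 0.0352) fell in the authors' deposited table. Counts adjusted over the list alone were 1 for sodium, 5 for potassium and 3 for calcium channels, 2 for glutamate receptors, 1 for GABA and glycine receptors and 1 for presynaptic genes.

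Of 19 tested unfolded protein response genes, 3 rose and 1 fell in the authors' deposited table, with 5 called when adjusted over the list alone. The endoplasmic reticulum chaperone gene Sdf2l1 rose 1.85-fold (17.3 to 32 FPKM, q = 0.00241), Creld2 1.62-fold and the transcription factor gene Xbp1 1.43-fold (q = 0.0332), while Dnajb9 fell 1.72-fold in the authors' deposited table. The list's median log2 fold change of 0.30 lay at percentile 99.9, and Fisher's exact test for higher genes gave an adjusted p of 0.154. Of 19 sterol synthesis genes, Lss (1.74-fold), Hsd17b7 (1.66-fold, q = 0.0324) and Fdps (227 to 354 FPKM, 1.56-fold) rose and none fell in the authors' deposited table, with 3 adjusted over the list alone. Of 76 respiratory chain genes, Cox6a1 (495 to 887 FPKM), Ndufs2 (118 to 208 FPKM), Ndufv1 (q = 0.0282) and Cyc1 (q = 0.0311) rose and none fell in the authors' deposited table, with 2 adjusted over the list alone. No heat shock (11 tested) or antioxidant gene (17 tested) passed the test in the authors' deposited table. Single members passed elsewhere in the authors' deposited table: Psmc5 rose among 31 proteasome genes (q = 0.0457), Gabarap fell among 23 autophagy and lysosome genes (q = 0.0212), and Ifih1 rose among 10 interferon response genes. Of 31 ALS genes, the kinase gene Nek1 rose 2.01-fold (20.1 to 40.4 FPKM, q = 0.000711) and Ubqln2 fell 1.44-fold (q = 0.0372) in the authors' deposited table. Dync1i1 rose (q = 0.0450) and Dpysl2 fell (q = 0.0224) among 24 axon cytoskeleton and transport genes, and Gadd45b (q = 0.0210) and Bbc3 fell among 17 p53 and apoptosis genes in the authors' deposited table. Adjusted over the list alone, 0 proteasome, 0 autophagy, 1 interferon, 1 ALS, 0 axon and 2 p53 genes were called.

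Among cell type lists in Ctip2+ neurons, 4 of 18 callosal genes rose in the authors' deposited table: Cpne4 (17.1 to 37.7 FPKM, 2.2-fold), Chn2 (1.85-fold), Unc5d (1.68-fold) and Dkk3 (1.61-fold). Cpne4 and Dkk3 were higher in Ctip2+ than in Satb2+ neurons of hSOD1WT mice (17.1 against 4.12 and 57.3 against 26.5 FPKM) in the authors' deposited table, so they did not mark callosal neurons here. The list's adjusted p of Fisher's exact test was 0.0192, and 5 were called over the list alone. Its median log2 fold change of 0.10 lay at percentile 82.3 of random lists, with 10 members above 0 and 8 below. Of 13 subcerebral genes, Etv1 rose 1.48-fold (q = 0.0271) and S100a10 fell 1.66-fold (292 to 175 FPKM) in the authors' deposited table, and of 7 corticothalamic genes, Tle4 rose 1.65-fold and Ntsr1 fell 1.59-fold (q = 0.0336), with 2 over the list alone in each. Nxph1 rose (q = 0.0498) among 10 interneuron genes in the authors' deposited table, whose median log2 fold change was -0.54, with 0 called over the list alone. Of 7 astrocyte genes, Aldoc rose (8.05 to 16 FPKM) and Gfap fell (1.21 to 0.141 FPKM, q = 0.0121) in the authors' deposited table, and 2 were called over the list alone. No striatal (7 tested), oligodendrocyte lineage (4), microglia (2), vascular (4) or cycling progenitor gene (2) passed the test in the authors' deposited table, and adjusted over the list alone 1 vascular and 1 progenitor gene did. The hemoglobin gene Hba-a2, the only blood gene tested, fell from 11.4 to 3.76 FPKM (q = 0.0139) in the authors' deposited table. Of 13 immediate early genes, Egr4 fell 2.73-fold (15.4 to 5.64 FPKM) and Jund 1.51-fold in the authors' deposited table, with 2 over the list alone. None of the 5 tested members of the list of Y-linked genes and Xist passed the test in the authors' deposited table. Of them, 3 lay below 0, with Eif2s3y at 54.0 and 39.3 FPKM, and 2 above, Kdm5d (2.12 to 2.90 FPKM) and Xist (6.07 to 9.06 FPKM).

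List medians in Ctip2+ neurons, from fold changes in the authors' deposited table and without regard to calls, lay at percentile 99.0 of random lists for striatal (0.39), 99.0 for glutamate receptor (0.20) and 98.4 for sterol synthesis genes (0.20). They lay at percentile 0.25 for interneuron, 1.47 for potassium channel (-0.13) and 0.80 for the authors' synaptic transmission genes (-0.04) in the authors' deposited table. Against lists matched on GC content, length and expression, the percentiles were 6.5 for potassium channel and 3.7 for synaptic transmission genes, and quantile normalization took the glutamate receptor median to 0.15 and out of the outer 5% of random lists.

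The largest falls in Ctip2+ neurons included Rgma, an axon guidance gene (chromosome 7, 80454796 to 80564785), which went from 24.3 to 6.08 FPKM (4.00-fold, q = 0.000711) in the authors' deposited table. Epn1, an endocytosis adaptor (chromosome 7, 5031907 to 5049778), fell 3.89-fold (13.0 to 3.34 FPKM, q = 0.000711) in the authors' deposited table. Lmtk3, Khsrp, Gpr25, Mmp15, Chst2, linc-Galntl5 and linc-Fstl4-AS fell between 3.36-fold and 4.04-fold in the authors' deposited table, and the linc entries among them were not called when adjusted within the comparison. The non-coding entry linc-Parp2-AS is listed at 0 FPKM in G93A, and Lars2 went from 6114 to 1819 FPKM (q = 0.0114) in the authors' deposited table. Among the largest rises, Myh6, a cardiac myosin gene (chromosome 14, 55560758 to 55585444), went from 0.168 to 8.23 FPKM (49.0-fold, q = 0.000711, log2 fold change 2.98 with log2(value + 1)), and Aoc3 from a listed 0 to 1.90 FPKM in the authors' deposited table. The orexin receptor gene Hcrtr2 (chromosome 9, 76073687 to 76171385) rose 2.90-fold from 1.14 to 3.32 FPKM, and the synaptotagmin gene Syt10 rose 2.70-fold from 2.71 to 7.32 FPKM in the authors' deposited table. Spag16, Klhl3, AK164331, Crabp1, Ifih1, Bbx, Tbc1d8b and Enpep rose between 2.66-fold and 4.53-fold in the authors' deposited table, but Spag16, AK164331, Crabp1 and Enpep were not called when adjusted within the comparison. Mouse Sod1 (chromosome 16, 90220987 to 90226569) stood at 164 and 136 FPKM (q = 0.381), Bcl11b had q = 0.761, Satb2 q = 0.277 and Fezf2 q = 0.216 in the authors' deposited table.

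G93A against hSOD1WT in Satb2+ neurons asks the same of neurons that stay within the cortex. All 6 tested vascular genes fell, 4 of 13 immediate early genes and 5 of 19 GABA and glycine receptor genes rose, and Nrgn was the only called gene of the postsynaptic density, where it rose. Of 13786 tested genes, 414 were called higher and 392 lower in the authors' deposited table, 806 in all or 5.85%. Adjustment within the comparison left 182 higher and 157 lower. Long transcripts were called lower more often: 96 of the 1091 genes in the longest 10% (8.80%) were called lower and 13 higher in the authors' deposited table.

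All 6 tested vascular genes fell, with a median log2 fold change of -2.49, below all 10000 random lists, and a Fisher's exact adjusted p of 7.13e-08 in the authors' deposited table. All 6 were also called when adjusted over the list alone, and 4 when adjusted within the comparison. Kdr, the VEGF receptor (chromosome 5, 76329299 to 76374453), fell 11.8-fold (2.12 to 0.179 FPKM) and Cldn5, an endothelial tight junction gene (chromosome 16, 18776940 to 18778355), 8.58-fold (20.9 to 2.44 FPKM), both at q = 0.000711 in the authors' deposited table. Flt1 (5.78-fold), Pecam1 (5.47-fold), Vtn (q = 0.0174) and Esam (q = 0.0183) fell too in the authors' deposited table. The largest fall of all named genes in this comparison was that of Ctla2a (5.39 to 0.388 FPKM, 13.9-fold), and Slc22a8, Pglyrp1, Gng11, Slc38a5, Il2rg, Fam176b, Htra3, Tie1 and the hemoglobin gene Beta-s fell between 6.96-fold and 11.3-fold in the authors' deposited table. Of these, Pglyrp1, Gng11, Il2rg and Fam176b were not called when adjusted within the comparison. Of 2 blood genes, Hba-a2 fell from 34.8 to 10.3 FPKM (q = 0.000711) in the authors' deposited table, with 2 over the list alone. Of 7 microglia genes, C1qb (2.81 to 0.634 FPKM, q = 0.0258) and C1qa (q = 0.0485) fell in the authors' deposited table, with 2 over the list alone and a list median of -1.79. Fabp7 fell 2.15-fold (51.0 to 23.7 FPKM) and Slc1a2 rose 1.47-fold (q = 0.0396) among 6 astrocyte genes in the authors' deposited table, with 2 over the list alone. No oligodendrocyte lineage (4 tested) or cycling progenitor gene (1 tested) passed the test in the authors' deposited table, while 1 of each did over the list alone.

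Of 13 tested immediate early genes, 4 rose and none fell in the authors' deposited table, with 8 called over the list alone and a Fisher's exact adjusted p of 0.00924. Arc, which acts at synapses (chromosome 15, 74499513 to 74503000), rose 3.19-fold (1.11 to 3.53 FPKM, q = 0.000711) and Egr1 1.98-fold (22.1 to 43.9 FPKM, q = 0.000711) in the authors' deposited table. Fos (2.11-fold, q = 0.0132) and Egr3 (1.75-fold, q = 0.0107) rose as well in the authors' deposited table. Of 19 GABA and glycine receptor genes, 5 rose and 1 fell in the authors' deposited table, with 7 over the list alone and a Fisher's exact adjusted p of 0.0051. Gabrd rose 1.87-fold (7.72 to 14.4 FPKM) and Gabra4 1.59-fold (47.6 to 75.5 FPKM), Glra2 (q = 0.0386), Glrb and Gabra1 (q = 0.0198) rose too, and Gabrg3 fell 2.23-fold (14.1 to 6.32 FPKM) in the authors' deposited table. Of 23 presynaptic genes, Snap25 (388 to 587 FPKM, q = 0.0271), Syn2 (q = 0.0230) and Vamp2 (q = 0.0369), all of vesicle release, rose and none fell in the authors' deposited table, with 3 over the list alone, none when adjusted within the comparison and a Fisher's exact adjusted p of 0.261. Nrgn rose 1.58-fold (303 to 478 FPKM, q = 0.00847) among 18 postsynaptic density genes in the authors' deposited table, with 1 over the list alone and a list median of -0.02.

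**Figure D2:**
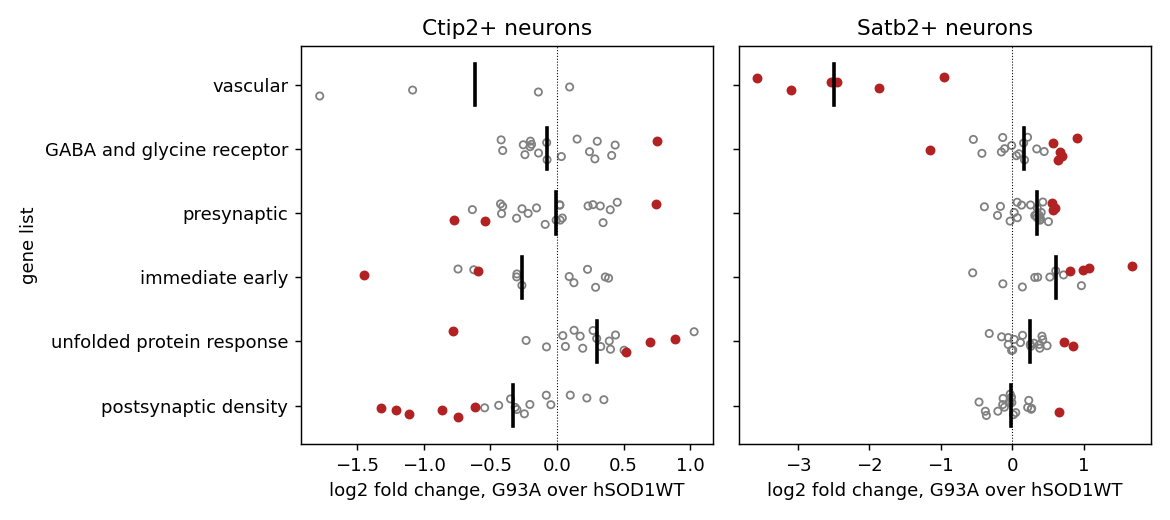
Log2 fold change of G93A over hSOD1WT for the tested members of 6 gene lists in Ctip2+ and Satb2+ neurons, 1 point per gene, from the authors' deposited table; red points passed q below 0.05, open points did not, bars are list medians, and the panels have different scales. Of 18 postsynaptic density genes 6 fell in Ctip2+ neurons, and all 6 vascular genes fell in Satb2+ neurons.

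Among the other neuronal lists in Satb2+ neurons, Scn2b rose 1.79-fold among 8 sodium channel genes, and Kcns1 (1.86-fold) and Kcnab1 (q = 0.0142) rose and Kcnj2 fell 2.59-fold among 58 potassium channel genes in the authors' deposited table. Cacnb4 rose 1.64-fold and Ryr1 (2.00-fold) and Cacna1b (q = 0.0427) fell among 27 calcium channel genes in the authors' deposited table. Grik1 and Grm4 (q = 0.0441) rose and Grik4 (q = 0.0192) and Grin3a (q = 0.0476) fell among 22 glutamate receptor genes in the authors' deposited table. Over each list alone, 1 sodium channel, 3 potassium channel, 2 calcium channel and 4 glutamate receptor genes were called. Striatal genes that rose included Ppp1r1b (q = 0.0230) and Gpr6 (q = 0.0161) in the authors' deposited table. Ldb2 fell 1.76-fold (26.5 to 15 FPKM) among 12 subcerebral genes, Sla fell (q = 0.0195) among 7 corticothalamic genes, and Btg1 rose (q = 0.0135) and Epha3 fell 1.70-fold among 20 callosal genes in the authors' deposited table. The neuropeptide gene Npy fell from 118 to 71.1 FPKM (q = 0.0107) among 6 interneuron genes in the authors' deposited table. Over each list alone, 1 subcerebral, 1 corticothalamic, 2 callosal and 3 interneuron genes were called.

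List medians in Satb2+ neurons, from fold changes in the authors' deposited table and without regard to calls, lay at percentile 100 of random lists for presynaptic (0.35), 99.6 for respiratory chain and 99.3 for unfolded protein response genes (0.25). They lay at percentile 0.010 for calcium channel (-0.31), 0.10 for glutamate receptor (-0.25), 0.050 for axon cytoskeleton and transport (-0.06), 0.020 for microglia, 0.57 for interneuron (-0.57) and 2.99 for astrocyte genes (-0.42) in the authors' deposited table. Against lists matched on GC content, length and expression, the percentiles were 97.2 for unfolded protein response, 3.69 for glutamate receptor and 3.08 for axon cytoskeleton and transport genes.

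Of 76 respiratory chain genes, Cycs, cytochrome c (104 to 237 FPKM, 2.28-fold, q = 0.000711), Cox7c (1.71-fold), Ndufc1 (1.70-fold) and Cox8a (q = 0.0446) rose and none fell in the authors' deposited table, with 3 over the list alone. The list's median log2 fold change was 0.23, against 0.15 for random lists of like expression, and 0.07 with quantile normalization. Of 19 unfolded protein response genes, Sdf2l1 (1.79-fold, q = 0.0139) and Dnajb9 (1.65-fold) rose in the authors' deposited table, with 2 over the list alone. Cryab (q = 0.0355) and Hspe1 (q = 0.0410) rose among 11 heat shock genes, Tuba4a (105 to 179 FPKM, 1.70-fold) and Vapb (q = 0.0114) rose among 31 ALS genes, and Ccng1 (q = 0.0111) and Sesn1 (q = 0.0322) rose among 15 p53 and apoptosis genes in the authors' deposited table, with 2 over the list alone in each. No antioxidant (16 tested), proteasome (31), autophagy and lysosome (23), sterol synthesis (19), interferon response (8) or axon cytoskeleton and transport gene (24) passed the test in the authors' deposited table, or over the list alone. The largest rises among protein-coding genes included the calcium-binding protein gene Calb1 (chromosome 4, 15808411 to 15833856), from 6.48 to 19.2 FPKM (2.96-fold, q = 0.000711), and Col8a1 (2.91-fold) in the authors' deposited table. The non-coding entry linc-Mtpn-2 rose from 51.2 to 279 FPKM (5.44-fold, q = 0.000711), and AK139182, linc-Klf11, linc-Tmco1-AS, Ube2h, Neu3, AK031819, linc-Thumpd3-AS and Dapk2 rose between 2.66-fold and 5.48-fold in the authors' deposited table. Of the latter, only Neu3 and linc-Thumpd3-AS were called when adjusted within the comparison. Mouse Sod1 stood at 130 and 123 FPKM (q = 0.849), Satb2 had q = 0.998, Fezf2 q = 0.955, and Bcl11b was not tested in the authors' deposited table. The Y-linked genes Eif2s3y (59.4 to 32.5 FPKM, q = 0.000711), Uty (q = 0.0279) and Kdm5d (q = 0.0355) fell in the authors' deposited table. The other 2 tested members of their list, Ddx3y (7.62 to 5.28 FPKM, q = 0.0713) and Xist (11.6 to 17.7 FPKM, q = 0.119), did not pass the test in the authors' deposited table, and Xist lay in the other direction. All 5 were called over the list alone, and the Fisher's exact adjusted p for lower genes was 0.0051. The list median of -0.87, which mixes Y-linked genes with Xist, lay below all random lists. The labels give no sex, so a different share of males in the G93A libraries cannot be told apart from the genotype.

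Genotype effects were also set side by side to ask which responses the populations shared. Of 13059 genes tested in both, 93 were called in both in the authors' deposited table, 60 in the same direction (24.1 expected if the calls were independent) and 33 in opposite directions (24.8 expected). Of the 33, 18 were higher in Ctip2+ and lower in Satb2+ neurons (9.06 expected) and 15 the reverse (15.8 expected), so the latter were no more than independent calls would give. Adjustment within each comparison left 23 and 10, and the 10 were 3 (1.61 expected) and 7 (3.85 expected). Of the genes named next for the same direction, Sdf2l1, Kcnab1, linc-Esp38 and Foxo6 were not called in Satb2+ neurons by that adjustment. Calcium channel subunit Cacnb4, GABA receptor subunit Gabra4, chaperone gene Sdf2l1, Kcnab1, Flrt2, Car10 and Crtac1 rose in both, and linc-Esp38 (chromosome 17, 39979942 to 39985774, 1733 to 520 and 769 to 382 FPKM), Zrsr1, Hba-a2, the vascular basement membrane collagen gene Col4a1 and Foxo6 fell in both in the authors' deposited table. Opposite calls included Nrgn, Calb1 (24.1 to 13.8 FPKM in Ctip2+), Vsnl1 (54.4 to 33.2 and 74.1 to 127 FPKM), Bhlhe22 (64.6 to 38.5 and 26.1 to 55.9 FPKM) and Dnajb9, which fell in Ctip2+ and rose in Satb2+ neurons in the authors' deposited table. The other class included Commd4 (197 to 296 and 660 to 114 FPKM), N4bp2 (1.39 to 2.90 and 2.08 to 0.916 FPKM), Brwd3, Bicd1 and Ash1l in the authors' deposited table. When adjusted within the comparison, the last 3 were not called in Satb2+ neurons, and Ash1l (q = 0.0158 in Ctip2+) was not called in Ctip2+ neurons either. Across 12230 genes, which are not independent replicates, the log2 fold changes of the comparisons correlated with Pearson r = 0.10 and Spearman rho = 0.12. Both comparisons shared a GC trend: the Spearman rho of GC content and log2 fold change was -0.13 in Ctip2+ and -0.11 in Satb2+ neurons (10907 genes). The counts expected from independent calls take no account of that trend, and its part in the overlap was not tested. The difference between the populations was not tested.

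**Figure D3:**
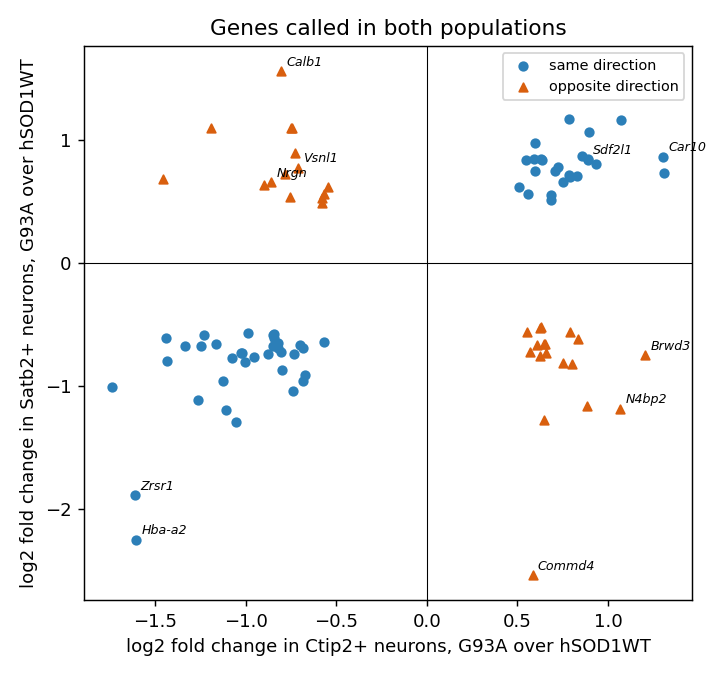
Log2 fold change of G93A over hSOD1WT in Ctip2+ neurons (x axis) and in Satb2+ neurons (y axis) for the 93 genes called in both comparisons of the authors' deposited table, 1 point per gene. Circles are the 60 genes called in the same direction and triangles the 33 called in opposite directions.

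The authors' own lists were counted as well. They are not independent evidence if they were chosen on these samples, which is not stated. In Ctip2+ neurons, 18 of 397 synaptic transmission genes rose and 42 fell in the authors' deposited table (adjusted p of Fisher's exact test for lower genes 2.55e-07, 58 over the list alone), and 11 of 197 glutamatergic synapse genes rose and 18 fell (adjusted p 0.0121, 29 over the list alone). In Satb2+ neurons, 28 of 395 synaptic transmission genes rose and 8 fell in the authors' deposited table (adjusted p of Fisher's exact test for higher genes 0.0011, 18 over the list alone), and 14 of 195 glutamatergic synapse genes rose and 5 fell (adjusted p 0.0293, 10 over the list alone). Of the authors' sodium channels, 1 of 10 fell in Ctip2+ and 1 of 9 rose in Satb2+ neurons in the authors' deposited table, with 1 over the list alone in each. Of the authors' potassium channels, 2 rose and 2 fell of 51 in Ctip2+ neurons, and 1 rose and 1 fell of 54 in Satb2+ neurons in the authors' deposited table, with 2 over the list alone in each.

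**Figure D4:**
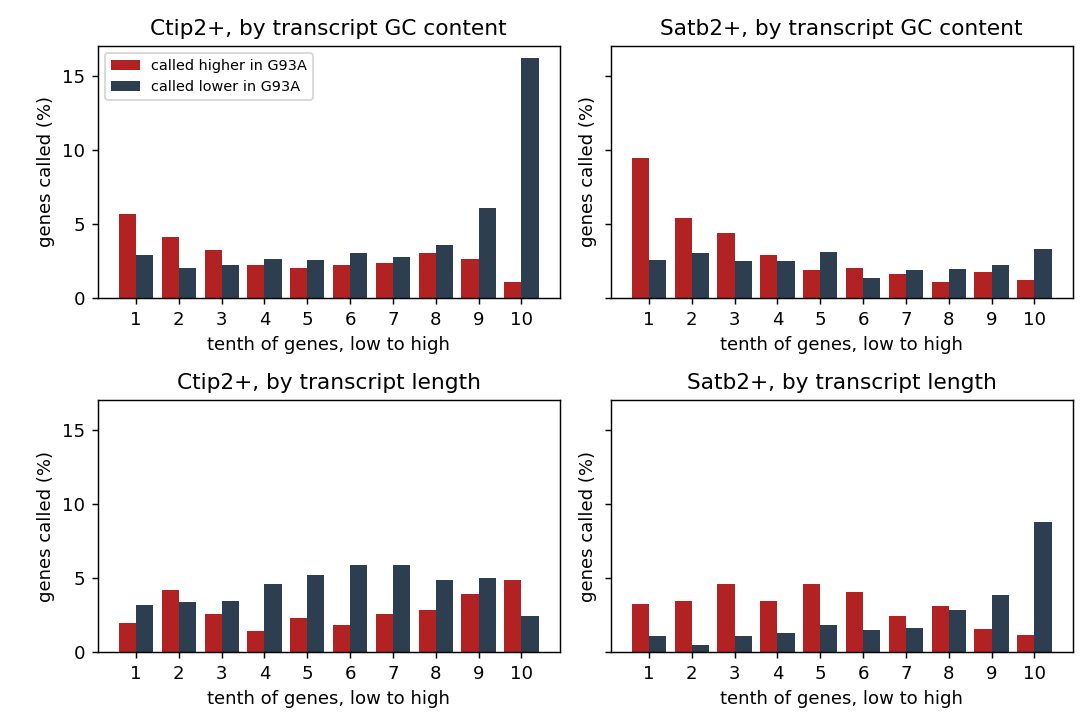
Percent of genes called higher (red) and lower (dark) in G93A in 10 equal parts of transcript GC content (top) and transcript length (bottom), for Ctip2+ (left) and Satb2+ neurons (right), from calls in the authors' deposited table and 10907 genes with a GC and length value. In Ctip2+ neurons 16.2% of the most GC-rich part were called lower, and in Satb2+ neurons 8.80% of the longest part were called lower and 9.44% of the part with the lowest GC content were called higher.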

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

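Adjustment within each comparison, genes alone at their locus, GC-matched lists, quantile normalization of the lists, the sets without GC-rich or vascular-range genes and the 10 FPKM filter were chosen after the results were seen. At a deposited q below 0.01, Ctip2+ neurons had 419 calls in place of 928 (152 higher, 267 lower), Satb2+ neurons 325 in place of 806 (173 higher, 152 lower), and both shared 19 genes in the same direction and 8 in opposite directions. Adjustment within each comparison gave 476 (177 higher, 299 lower), 339 (182 higher, 157 lower), 23 and 10. Both are stricter, which lowers counts by construction. Without the most GC-rich 10% of genes, 352 genes were lower in Ctip2+ neurons, by construction. The 4-fold counts between sorts were 337 and 315 (hSOD1WT) and 449 and 356 (G93A) with log2(value + 0.1), since a smaller pseudocount widens ratios of low values. At 10 FPKM, the filter first used, 82 entries were higher in Ctip2+ hSOD1WT neurons, since fewer were counted. All other alternatives for these counts stayed within 1.5 times, including the set without genes of the vascular range, which selects on the outcome.

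Of 295 named values, none reversed; 59 lost their call within the comparison and 67 at q below 0.01, and 33 moved by over 1.5-fold with log2(value + 1), 35 with quantile normalization and 4 with log2(value + 0.1). Of 65 list medians, those matched on GC content, length and expression gained 3 places in the outer 5% of random lists and lost 6, 20 steps of GC content gained 1 and lost 3, quantile normalization gained 1 and lost 2, and log2(value + 0.1) changed none. The postsynaptic density in Ctip2+ neurons and the vascular and immediate early lists in Satb2+ neurons kept theirs in each. The vascular median of -2.49 was -0.90 with quantile normalization of log2(value + 1), which shrinks folds of low values by construction, and -2.11 with log2(value + 0.1). The potassium channel list and the authors' potassium channel and synaptic transmission lists in Ctip2+ neurons lost theirs with both GC matchings. The unfolded protein response, glutamate receptor and axon cytoskeleton lists in Satb2+ neurons lost theirs when matched on GC content, length and expression, and quantile normalization ended that of the unfolded protein response in Satb2+ and of glutamate receptors in Ctip2+ neurons; the cause was not tested.

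No paired analysis was possible because the deposited table holds pooled values and none per library. For the same reason fits on fewer groups, left-out libraries, no age term, each age alone, the replicate block, an estimated correlation within lists and P7 against P5 were not run. Quantile normalization and other pseudocounts could not be applied to counts by the authors' q. Read depth is unknown, so what it limits cannot be said.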

Other observations

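The tests of transcript length in genes called in opposite directions, of astrocyte and oligodendrocyte markers, and of vessel number were chosen after the results were seen, and the reading of the length test was made stricter after its value was seen.

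Immediate early genes stood apart between the populations: the list's median log2 fold change was 0.61 in Satb2+ neurons and -0.26 in Ctip2+ neurons in the authors' deposited table, and the difference was not tested. Egr4, which fell in Ctip2+ neurons from 15.4 to 5.64 FPKM, stood at 4.50 and 7.40 FPKM in Satb2+ neurons in the authors' deposited table. Respiratory chain genes were higher in Ctip2+ than in Satb2+ neurons of hSOD1WT mice by a median log2 ratio of 0.52, above all random lists of like expression. Their median log2 fold change in G93A was 0.23 in Satb2+ and -0.00 in Ctip2+ neurons in the authors' deposited table, against 0.15 and 0.03 for random lists of like expression, and was 0.07 in Satb2+ neurons with quantile normalization.

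Postsynaptic density genes and GC-rich transcripts were both lower in G93A Ctip2+ neurons. A GC-linked difference between libraries was argued against as the whole cause of the first: among random lists matched on GC content, length and expression, the list's median still lay at percentile 0.15. The GC trend was in turn not confined to synaptic and channel genes, since the GC-rich 10% without them had a median log2 fold change of -0.17 over 1015 genes (bootstrap -0.20 to -0.14). A technical GC effect on part of the calls may remain, because GC content cannot be compared library by library. An effect of mutant SOD1 on these genes stays open, as untested.

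Opposite transcript length trends were weighed for the genes called in opposite directions. The geometric mean length of those called higher in Ctip2+ and lower in Satb2+ neurons was 2.56 times that of the others, which decides nothing, because genes called lower in Satb2+ neurons were longer anyway (median 5478 nt against 2842 nt for those called higher). The Spearman rho of length (10907 genes) was -0.31 in the Satb2+ but 0.0056 in the Ctip2+ comparison, which goes against an overall opposite trend, while among the longest 10% of genes 53 were called higher and 27 lower in Ctip2+ neurons in the authors' deposited table, which goes with one, so this explanation cannot be told apart from the genotype. Such a trend was argued against for the higher immediate early list in Satb2+ neurons, whose median lay at percentile 100 of lists matched on GC content, length and expression. A biological difference between the populations stays open, as untested.

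Vascular genes were lower in Satb2+ G93A neurons. Fewer vascular cells, or less of their RNA, in the Satb2+ G93A than in the Satb2+ hSOD1WT libraries is a candidate explanation. A second vascular list, written before its values were seen, had a median log2 fold change of -1.50. Of its 16 tested genes 14 lay below 0, and Anxa3, Cd93, Ets1, Nostrin and Slco1a4 were called lower (Cd93 and Ets1 also within the comparison). The sort was for nuclear SATB2, but Cldn5 stood at 20.9 FPKM in Satb2+ hSOD1WT neurons in the authors' deposited table, so vascular RNA was not all removed. A lower share of all non-neuronal cells alike was argued against, because astrocyte and oligodendrocyte lineage genes had a median of -0.40 (quartiles -0.54 to -0.27) against -2.49 (-2.96 to -2.02), although microglia genes had one of -1.79 (-1.91 to -0.97) and Hba-a2 of blood fell 3.38-fold in the authors' deposited table. Fewer vessels in the G93A cortex cannot be told apart from fewer vascular cells in the libraries. Of the vascular list, 4 genes near the floor could be read in Ctip2+ neurons (median -0.61, from -1.78 to 0.10). Of these, Cldn5 (2.74 to 2.49 FPKM) and Esam (2.88 to 3.07 FPKM) were the most abundant and did not pass the test in the authors' deposited table. Outside that list, Col4a1 (6.22 to 3.00 FPKM, q = 0.000711) and Hba-a2 (11.4 to 3.76 FPKM, q = 0.0139) fell in Ctip2+ neurons in the authors' deposited table. Fewer vessels would give such falls too, but single genes do not decide it. The 6 vascular genes tested in Satb2+ neurons were a median of 4.04 times as high there as in Ctip2+ neurons of hSOD1WT mice (0.895 times in G93A). Over 7 genes at 1 FPKM or more, the median log2 ratio of Ctip2+ over Satb2+ was -0.99 in hSOD1WT and 0.10 in G93A. By these medians Satb2+ hSOD1WT stood apart and Satb2+ G93A lay near Ctip2+ G93A, with Cldn5 at 2.44 FPKM in Satb2+ G93A. Vtn was less apart, at 1.24 FPKM in Ctip2+ and 1.73 FPKM in Satb2+ hSOD1WT neurons in the authors' deposited table. A surplus of vascular RNA in the Satb2+ hSOD1WT libraries cannot be told apart from a loss in G93A. An effect of mutant SOD1 stays open, as untested.

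Aoc3 stood at 0 and 1.90 FPKM in Ctip2+ hSOD1WT and G93A neurons, and at 0.0570 and 2.10 FPKM in Satb2+ neurons (q = 0.453), in the authors' deposited table. Myh6 stood at 0.168 and 8.23 FPKM in Ctip2+ neurons, and at 0.211 and 0.143 FPKM in Satb2+ neurons, in the authors' deposited table. The non-coding entry linc-Esp38 stood at 1733 and 520 FPKM in Ctip2+ and at 769 and 382 FPKM in Satb2+ neurons, and Lars2 at 6114 and 1819 and at 2964 and 2123 FPKM (q = 0.660 in Satb2+), in the authors' deposited table.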
